A study of Mus musculus with 35 samples.

How the data were processed

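RNA from NMuMG mouse mammary epithelial cells was measured by RNA sequencing in 35 samples, of which 20 form an inhibitor experiment (DMSO or JNKi, 5 times, 2 replicates per group) and 15 a TGF-β time course (5 times, 3 replicates per group). Groups, times and replicate numbers were taken from the sample titles. The labels do not say that replicates came from separate cultures, so p values measure only the spread between these samples, which may be technical. Per the submitters' processing notes, which give no versions, TopHat, HTSeq, DESeq and the mouse build mm9 were used. How low genes were removed and whether counting used strand are not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain.

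For the inhibitor experiment the authors deposited a normalized read count signal per gene and library, with 20261 genes and 1 decimal. Low values in each library were whole multiples of 1 step, so each value was divided by that step to recover reads; 100% of the values above 0 in every library lay within 0.1 of a whole number. These reads gave the depth of each library, from 9.5 to 48.6 M reads, and precision differs between libraries accordingly. For the time course the authors deposited other values: each normalized value had been split at its decimal point into separate cells, and 95.7% of 11405 genes with a cell of 100 or more jumped both ways between under 10 and 100 or more along the row. A cell could therefore not be assigned to a library, and the 4 planned comparisons with 0 h and the planned overlap with JNKi were not run. The overlap was replaced, after seeing the data, by DMSO at 96 h against 24 h beside JNKi against DMSO at 7 days.

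The comparisons, tests, gene lists, rule for naming genes and alternatives were fixed before the data were examined, except where stated. The log2 of the deposited value plus 1 was analysed with limma 3.58.1 (R 4.3.3), with an intensity trend, one mean per group and all 20 libraries in a single model, for 13896 genes with a mean of at least 10 in at least 1 group. Tests were two-sided and p values were adjusted by Benjamini-Hochberg over those genes, with 0.05 as the threshold. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and SE is the model's standard error. The JNKi contrasts were JNKi against DMSO at each time, their mean over 5 times, and an F-test of the 4 differences between each later JNKi effect and that at 24 h; the DMSO contrast was 7 days against 24 h. A contrast of 7 days against the mean of the 4 earlier times and the mean over 24 to 96 h were added after seeing the data.

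The 30 gene lists came from general knowledge and covered epithelial junctions, keratins, mesenchymal cytoskeleton, extracellular matrix, matrix proteases, EMT transcription factors, TGF-β signalling, AP-1, the JNK pathway, immediate-early genes, G2/M, DNA replication, p53 targets, the unfolded protein response, cholesterol biosynthesis, interferon, NF-kB, aryl hydrocarbon receptor, oxidative stress, YAP/TEAD, glycolysis, Wnt, luminal, basal, leukocyte, endothelial and adipocyte markers, ribosomal proteins, mitochondrially encoded genes and histones. Some genes stand in more than 1 list. They were tested with camera at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation and with fry; camera calls hold with an estimated correlation only where that adjusted p, given beside the call, is under 0.05. Named genes were, for the JNKi mean, the 8 largest each way with the same sign at all 5 times; at 7 days, the 4 largest each way without overlap between replicates; for the overlap, the 6 with the largest sum of both changes in each opposed direction. A group mean of at least 50 was required. Mapk8, Mapk9, Jun, Cdh1, Cdh2, Vim, Fn1, Snai1, Zeb1 and Zeb2 were always named (1 further gene is not reported here), and each list gave up to 4 members, the 2 largest changes past the test and the 2 highest means. No gene passed at 24 h, so none was named from that time.

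The tests were run on simulated counts with 200 genes changed by known folds. For a change at 7 days alone, on 13024 genes, 44.4%, 79.7% and 92.3% of genes changed 1.5-, 2- and 4-fold were recovered and 5.4% of calls fell on unchanged genes. For a change at all times, on 13010 genes, 90.5%, 92.4% and 100% were recovered. For a change at 24 h alone, on 13015 genes, 54.8%, 85.1% and 95.4% were recovered. The simulated counts were drawn independently around 1 mean per gene, without a change with time or likeness between same-number libraries. The rates may therefore differ from those of the real tests.

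The alternatives were other pseudocounts (0.5 and 8), no filter or a group mean of at least 50, TMM and upper quartile rescaling, limma without the trend and with robust variances, the replicate number as a block, the 2 groups compared alone, a log2 change of at least 1, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. A block of libraries of the same time and number and the subtraction of a background per kb of exon were added after seeing the data. The background was estimated from 514 olfactory and vomeronasal receptor genes, each under 1 RPM (reads per M reads) in every library, or from other silent tissue-restricted families; exon lengths came from a newer mouse annotation matched by symbol (98.7% of genes), and no coordinates were used. To compare depths, every library was thinned to 9492324 reads. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 recovered the reads and drew the plots.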

Results

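NMuMG, an epithelial line from the normal mouse mammary gland, undergoes an epithelial-mesenchymal transition (EMT), the loss of epithelial junctions and gain of mesenchymal traits, when given transforming growth factor β (TGF-β). RNA from these cells was sequenced in 35 samples. A TGF-β time course made up 15 of them, with 3 samples at each of 5 times, and its values were not analysed here. The other 20 came from cells kept with the vehicle DMSO or with an inhibitor of c-Jun N-terminal kinase (JNK), a stress-activated kinase that phosphorylates the transcription factor Jun. The labels call the inhibitor JNKi and do not name the compound, and the protocol given for all samples includes TGF-β at 2 ng/ml. Each arm had 2 samples at 24, 48, 72 and 96 h and at 7 days. The DMSO libraries (replicate 1 and replicate 2, in M reads) held 20.7 and 21.0 at 24 h, 25.5 and 21.6 at 48 h, 48.6 and 33.6 at 72 h, 42.8 and 32.5 at 96 h, and 16.7 and 40.9 at 7 days. The JNKi libraries held 25.8 and 18.8 at 24 h, 17.1 and 24.5 at 48 h, 36.9 and 35.5 at 72 h, 43.8 and 34.9 at 96 h, and 9.5 and 36.6 at 7 days. Replicates differed by more than sampling noise in every group, with a chi-square per degree of freedom from 8.8 (DMSO at 48 h) to 29.2 (JNKi at 7 days). Single genes with many reads weigh heavily in this value. In JNKi at 7 days the gene Lars2 stood at 15936 RPM in replicate 1 and 1699 RPM in replicate 2. The values therefore do not rank the groups by the likeness of their replicates. The first principal component (50.1% of the variance) followed time. The second (17.1%) placed the JNKi libraries of 7 days at 52.6 and 51.9 and the DMSO libraries of 7 days at 15.7 and 26.

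The first comparison asked how vehicle-treated cells changed between 24 h and 7 days. Tagln, which encodes the actin-binding protein transgelin, rose from 52.6 ± 3.04 to 8590 ± 1740 normalized reads (mean ± SD, n = 2), and Acta2, smooth muscle actin, rose from 18.5 ± 1.7 to 8610 ± 3110 (SD, n = 2). Fn1, the matrix glycoprotein fibronectin, rose from 48200 ± 6970 to 195000 ± 33800 normalized reads (SD, n = 2), a log2 fold change of 2.01 (SE 0.18, limma adjusted p = 1.32e-07). Cdh1, the epithelial junction protein E-cadherin, fell from 11100 ± 771 to 4070 ± 462 (SD, n = 2), a log2 fold change of -1.45 (SE 0.14, limma adjusted p = 2.98e-07). Cdh2, N-cadherin, rose by 1.18 (SE 0.09, limma adjusted p = 3.97e-08). The transcriptional repressors Zeb1 and Zeb2 rose by 0.89 (SE 0.10) and 1.22 (SE 0.11), whereas the intermediate filament gene Vim fell by 0.58 (SE 0.10). The repressor Snai1 had a log2 fold change of -0.66 (SE 0.22, limma adjusted p = 0.0183), a call lost without DMSO 24 h replicate 1 (0.11) or DMSO 7 d replicate 1 (-0.38, adjusted p = 0.237). For the JNK gene Mapk8 the log2 fold change was 0.35 (SE 0.13, limma adjusted p = 0.0326), and this call was lost without DMSO 24 h replicate 1 (0.22, adjusted p = 0.258), without DMSO 7 d replicate 1 (0.10, adjusted p = 0.539) and in a fit on the 4 libraries alone (0.156). Jun (0.29, limma adjusted p = 0.116) and the JNK gene Mapk9 (-0.06, adjusted p = 0.54) did not pass the test. Of 11 EMT transcription factors 3 rose and 7 fell (3 and 7 adjusted over the list alone), with a median of -0.44 and a camera adjusted p of 0.345.

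Matrix and adhesion genes rose with time as groups. Of the 35 extracellular matrix genes tested, 29 rose and 1 fell over all genes (30 and 1 adjusted over the list alone). Among them the fibroblast matrix gene Postn went from 0.7 ± 0.99 to 43 ± 1.27 normalized reads (SD, n = 2), and Lox, a collagen cross-linking enzyme, was listed at 0 at 24 h and at 23.3 ± 0.424 at 7 days. Camera gave the matrix list an adjusted p of 2.96e-08 (adjusted p = 0.115 with an estimated correlation). Matrix proteases and inhibitors rose in 19 and fell in 1 of 25 members (20 and 1 adjusted over the list alone), including the gelatinase gene Mmp9 at a log2 fold change of 4.12 (SE 0.34). Camera gave the proteases an adjusted p of 3.97e-05 (adjusted p = 0.115 with an estimated correlation). Mesenchymal cytoskeleton and adhesion genes rose in 16 and fell in 4 of 24 (16 and 4 adjusted over the list alone), with a camera adjusted p of 0.00101 (adjusted p = 0.185 with an estimated correlation). TGF-β signalling and feedback genes rose in 18 and fell in 4 of 31 (18 and 4 adjusted over the list alone), with the latent TGF-β binding protein gene Ltbp2 at 5.62 (SE 0.24). Camera gave the TGF-β list an adjusted p of 0.00754 (adjusted p = 0.185 with an estimated correlation). Targets of the mechanosensitive YAP/TEAD factors rose in 16 and fell in 2 of 20 (16 and 2 adjusted over the list alone), including Ankrd1 (2.01, SE 0.15) and Crim1 (2.13, SE 0.11). Camera gave the YAP/TEAD targets an adjusted p of 0.000288 (adjusted p = 0.185 with an estimated correlation). Wnt ligands, inhibitors and targets rose in 9 and fell in 1 of 14 (9 and 1 adjusted over the list alone), with Wnt7a at 3.35 (SE 0.18) and Wnt9a at 3.28 (SE 0.19). Camera gave the Wnt list an adjusted p of 0.00139 (adjusted p = 0.115 with an estimated correlation).

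Inflammatory genes also rose with time. NF-kB cytokines and chemokines rose in 22 and fell in 0 of 24 (23 and 0 adjusted over the list alone), with the chemokine gene Ccl20 at a log2 fold change of 5.85 (SE 0.37) and the granulocyte growth factor gene Csf3 at 4.02 (SE 0.42; 3.09 and 4.96 without DMSO 24 h replicate 1 and replicate 2). Camera gave the NF-kB list an adjusted p of 3.26e-07 (adjusted p = 0.185 with an estimated correlation). Interferon-stimulated genes rose in 24 and fell in 1 of 35 (24 and 1 adjusted over the list alone), with Ifi44 at 4.78 (SE 0.44) and the class I light chain gene B2m at 1.33 (SE 0.09). Camera gave the interferon list an adjusted p of 0.000318 (adjusted p = 0.185 with an estimated correlation). The p53 targets and cell cycle inhibitors rose in 15 and fell in 2 of 23 (16 and 2 adjusted over the list alone), with a camera adjusted p of 0.00754 (adjusted p = 0.185 with an estimated correlation). Replication-dependent histone genes rose in 12 of 16 (13 adjusted over the list alone), such as Hist2h3c1 at 5.35 (SE 0.34), and their near-identical copies leave single histone values uncertain. Camera gave the histones an adjusted p of 0.000368 (adjusted p = 0.212 with an estimated correlation).

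Proliferation and sterol synthesis genes fell with time. All 30 G2/M genes fell (30 adjusted over the list alone), including the topoisomerase gene Top2a at -1.20 (SE 0.10) and the mitotic kinase gene Aurkb at -1.78 (SE 0.16). Of 30 DNA replication genes 29 fell (29 adjusted over the list alone), including Pcna at -1.27 (SE 0.14). The camera adjusted p values of these lists were 1.17e-11 and 1.88e-11 (adjusted p = 0.228 with an estimated correlation for both). All 23 cholesterol biosynthesis genes fell (23 adjusted over the list alone), with the isomerase gene Idi1 at -2.61 (SE 0.19) and the demethylase gene Cyp51 at -1.93 (SE 0.14). Camera gave the cholesterol list an adjusted p of 5.57e-12 (adjusted p = 0.185 with an estimated correlation). Ribosomal protein genes fell in 38 of 39 (38 adjusted over the list alone), with a camera adjusted p of 8.92e-09 (adjusted p = 0.386 with an estimated correlation). Oxidative stress genes fell in 11 and rose in 4 of 16 (11 and 4 adjusted over the list alone), with the peroxiredoxin gene Prdx1 at -1.37 (SE 0.14) and Sqstm1 at 1.29 (SE 0.13). Camera gave the oxidative stress list an adjusted p of 0.00393 (adjusted p = 0.17 with an estimated correlation). Keratins fell in 7 and rose in 2 of 12 (7 and 2 adjusted over the list alone), with the luminal keratin gene Krt8 at -1.52 (SE 0.15) and the basal keratin gene Krt17 at 3.37 (SE 0.38). Camera gave the keratins an adjusted p of 0.0161 (adjusted p = 0.375 with an estimated correlation). Epithelial junction and polarity genes fell in 16 and rose in 6 of 29 (16 and 6 adjusted over the list alone), and the matriptase gene St14 rose by 1.95 (SE 0.19). Camera gave the junction list an adjusted p of 0.0328 (adjusted p = 0.212 with an estimated correlation). Glycolysis and hypoxia genes fell in 15 and rose in 6 of 25 (15 and 6 adjusted over the list alone), with a camera adjusted p of 0.043 (adjusted p = 0.611 with an estimated correlation).

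Endothelial markers rose in 4 of 6 (4 adjusted over the list alone) and leukocyte markers rose in 5 and fell in 1 of 7 (5 and 1 adjusted over the list alone), with camera adjusted p values of 0.0783 and 0.236. The most abundant members at 7 days were Csf1r (839 ± 58.1 normalized reads, from 466 ± 8.34 at 24 h) and Cd14 (745 ± 47.1, from 1640 ± 229) among leukocyte markers, and Flt1 (386 ± 3.96, from 430 ± 31.5) and Cdh5 (288 ± 21.1, from 73.1 ± 19.8) among endothelial markers (SD, n = 2). The endothelial adhesion gene Pecam1 was listed at 0 at 24 h and at 18.6 ± 7.14 normalized reads at 7 days (SD, n = 2). The leukocyte phosphatase gene Ptprc was listed at 0 and at 8.6 ± 4.53 (SD, n = 2). Reads on 514 olfactory and vomeronasal receptor genes, each near silent in these cells, summed to 2.47 and 2.0 RPM (reads per M reads) in the DMSO libraries of 24 h and to 9.37 and 7.84 RPM in those of 7 days. By limma 8329 of 13896 genes changed between 24 h and 7 days (4444 higher and 3885 lower), of which 2300 were higher and 721 lower by at least 2-fold. Of these calls 53.4% were higher, against 46.8% with a group mean of at least 50, 49.9% with DESeq2 and 60.2% with no filter. Between 24 h and 96 h, 8790 genes changed. Also not past camera were the AP-1 family (7 rose and 2 fell of 15), JNK pathway (7 and 6 of 25), immediate-early genes (6 and 5 of 23), unfolded protein response (9 and 7 of 22) and aryl hydrocarbon receptor targets (3 and 1 of 8), with adjusted p values from 0.283 to 0.832. Nor were luminal markers (5 and 5 of 10), basal markers (8 and 5 of 16) and adipocyte markers (1 and 1 of 3), with adjusted p values of 0.541, 0.443 and 0.667. No arm without TGF-β was sampled beside these times, so time in culture and TGF-β were not separated.

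The next comparison asked which genes JNKi altered at each time from 24 to 96 h. At 72 h the chemokine genes Ccl20 and Ccl7 were higher with JNKi by 2.45 (SE 0.37) and 2.05 (SE 0.35) on the log2 scale, and the collagenase gene Mmp13 by 1.54 (SE 0.25), with limma adjusted p values of 0.0163, 0.0318 and 0.0238. Ccl20 stood at 254 ± 145 normalized reads with JNKi and 42.3 ± 9.76 with DMSO, and Ccl7 at 301 ± 43.8 and 72.2 ± 13.9 (SD, n = 2). The latent TGF-β binding protein gene Ltbp3 fell by 0.68 (SE 0.09, limma adjusted p = 0.00391). The adhesion molecule gene Mcam was at -0.93 (SE 0.14) and the fibrillar collagen gene Col5a1 at -0.91 (SE 0.15), with limma adjusted p values of 0.0163 and 0.0264. In all, 10 genes changed at 72 h, 6 higher and 4 lower. The others, named after their values were seen, were Sprr2h (2.18), Bcl2l15 (1.5), Neurl3 (1.09) and Slc4a8 (-0.44). At 96 h 1 gene changed, Sprr2h, from a family of near-identical cornified envelope genes (1.63, SE 0.24, limma adjusted p = 0.0463), and this call was lost without any 1 library of another time than 72 h. No gene passed limma's test at 24 h or at 48 h. These counts are from the fit without a block. With a block within each time, a fit chosen after seeing the data, they were 19, 15, 334 and 99 at 24, 48, 72 and 96 h. At an unadjusted p under 0.05 the fit without a block gave 610 genes at 24 h, 521 at 48 h, 1125 at 72 h and 677 at 96 h. By chance 695 were expected. At these times the difference between replicates correlated between arms at 0.53 to 0.73 among 9605 genes with a mean of at least 200. The fit without a block counts this likeness as noise, so counts under 695 do not show that JNKi had no effect. With edgeR on the recovered reads 0, 0, 15 and 1 genes changed at these times, and with DESeq2 1, 2, 105 and 34. Leaving out 1 library of 72 h gave 0 (DMSO replicate 1 or JNKi replicate 2), 1 (DMSO replicate 2) or 16 (JNKi replicate 1) genes. The count at 24 h was 13 without DMSO 24 h replicate 1, 4 without JNKi 24 h replicate 1, 6 without either JNKi 48 h library, 7 without either JNKi 72 h library and 1 without either DMSO 48 h library, and that at 48 h was 4 without DMSO 48 h replicate 1 and 3 without JNKi 48 h replicate 1.

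As a group, extracellular matrix genes had negative median log2 differences at 48 h (-0.21), 72 h (-0.32) and 96 h (-0.22). Their camera adjusted p values were 3.82e-06, 1.61e-08 and 1.74e-09 (adjusted p = 0.345, 0.125 and 0.0924 with an estimated correlation). Over all genes 0, 1 and 0 of the 35 members fell at these times, and 0, 8 and 8 fell adjusted over the list alone. The p53 targets and cell cycle inhibitors had medians of 0.18 at 48 h and 0.26 at 72 h, with 0 of 23 members past the test over all genes and 5 and 7 higher adjusted over the list alone. Camera gave the p53 targets adjusted p values of 6.79e-08 and 9e-08 at these times (adjusted p = 0.0635 and 0.0818 with an estimated correlation). NF-kB cytokines and chemokines had medians of 0.39 at 48 h and 0.60 at 72 h, with camera adjusted p values of 3.1e-06 and 3.28e-08 (adjusted p = 0.466 and 0.259 with an estimated correlation). Over all genes 0 and 2 of their 24 members rose at these times, and adjusted over the list alone 1 rose at 48 h while 9 rose and 1 fell at 72 h. With fry the adjusted p values at 48 h and 72 h were 0.0365 and 0.013 for p53 targets. They were 0.413 and 0.032 for matrix genes and 0.613 and 0.0855 for NF-kB genes. At 24 h the G2/M and DNA replication lists both had a median of -0.21 and a camera adjusted p of 1.68e-09 (adjusted p = 0.476 with an estimated correlation), with 0 of 30 members past the test in either list, over all genes or adjusted over the list alone. Matrix genes did not pass camera at 24 h (median 0.08, adjusted p = 0.272), nor did NF-kB genes at 24 h (0.13, adjusted p = 0.0512) or 96 h (0.16, adjusted p = 0.244), or p53 targets at 24 h (0.04, adjusted p = 0.0577). At 96 h the p53 targets passed with a median of 0.08 (adjusted p = 0.0239, or 0.334 with an estimated correlation). The G2/M median was -0.02 at 48 h, -0.16 at 72 h and 0.10 at 96 h, with camera adjusted p values of 0.501, 0.000281 and 0.0314 (0.878, 0.743 and 0.689 with an estimated correlation). The DNA replication median was -0.03, -0.08 and -0.10, with 0.528, 0.0748 and 0.00619 (0.878, 0.832 and 0.689 with an estimated correlation).

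Other lists also passed camera before 7 days, none with an estimated correlation and none with a member past the test over all genes. At 24 h YAP/TEAD targets pointed up (median 0.12, camera adjusted p = 0.0243), as did cholesterol biosynthesis genes (0.16, 0.000146), basal markers (0.17, 0.00783) and junction genes (0.10, 0.0435), while unfolded protein (-0.03, 0.00241) and ribosomal protein genes (-0.09, 0.00032) pointed down. YAP/TEAD targets pointed down at 96 h (-0.16, 5.56e-05). Mesenchymal cytoskeleton and adhesion genes pointed down at 72 h (-0.15, 0.00153) and 96 h (-0.19, 5.23e-08; 0.0924 with an estimated correlation). Ribosomal protein genes pointed up at 48 h (0.07, 0.0129), 72 h (0.12, 0.000281) and 96 h (0.07, 0.0314), histones at 48 h (0.54, 0.000209) and 96 h (0.72, 6.74e-05), and interferon-stimulated genes at 72 h (0.11, 0.00439). At 96 h cholesterol biosynthesis genes (0.14, 0.00292), aryl hydrocarbon receptor targets (0.40, 0.0314) and adipocyte markers (1.37, 0.0314) pointed up and immediate-early genes (-0.17, 0.0291) down.

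**Figure D1:**
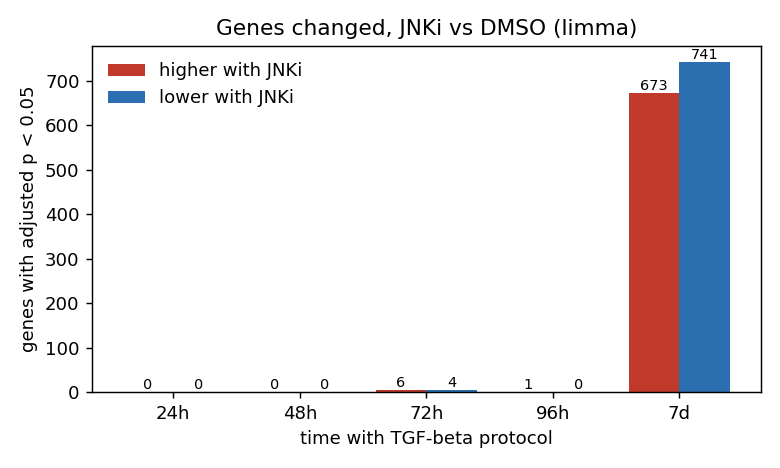
Number of genes higher (red) and lower (blue) with JNKi than with DMSO at each time (x axis), by limma without a block at an adjusted p under 0.05 among 13896 genes, with 2 libraries per arm and time. The bars read 0 at 24 h and 48 h, 6 and 4 at 72 h, 1 and 0 at 96 h, and 673 and 741 at 7 days.

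At 7 days the adhesion gene Mcam, the matrix genes Tnc and Fn1 and the contractile gene Tagln were lower in JNKi-treated than in vehicle-treated cells, while Acta2 (-0.37, limma adjusted p = 0.448) did not pass the test. Mcam stood at 1850 ± 56.8 normalized reads with JNKi and 5870 ± 157 with DMSO (SD, n = 2), a 3.17-fold lower level (log2 fold change -1.67, SE 0.14, limma adjusted p = 7.7e-06). Tnc, the matrix glycoprotein tenascin C, was lower by the same 3.17-fold (SE 0.13 on the log2 scale, limma adjusted p = 7.7e-06). Tagln was 3.09-fold lower at 2750 ± 66.5 against 8590 ± 1740, and Fn1 was 2.37-fold lower at 81800 ± 6920 against 195000 ± 33800 (SD, n = 2), with limma adjusted p values of 0.000282 and 0.000558. Mmp13 was 4.74-fold higher at 1130 ± 123 against 237 ± 24.4 normalized reads (SD, n = 2; limma adjusted p = 6.08e-05). Ccl20 was 4.88-fold higher at 4560 ± 1540 against 907 ± 12.2, and Ccl7 5.17-fold higher at 1770 ± 209 against 341 ± 27.2 (SD, n = 2). S100g, an epithelial calcium-binding protein, stood at 218 ± 7.14 in DMSO at 24 h, 27.8 ± 3.68 in DMSO at 7 days and 257 ± 40.1 with JNKi at 7 days (SD, n = 2). Zeb1 fell by 0.55 (SE 0.10) and Cdh2 was at -0.60 (SE 0.09), with limma adjusted p values of 0.00231 and 0.000981. Cdh1 (0.04, SE 0.14, limma adjusted p = 0.877), Vim (-0.09, adjusted p = 0.636), Snai1 (0.06, adjusted p = 0.895) and Zeb2 (-0.19, adjusted p = 0.288) did not pass the test. Nor did the JNK genes Mapk8 (-0.20, limma adjusted p = 0.358) and Mapk9 (0.11, adjusted p = 0.409).

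**Figure D2:**
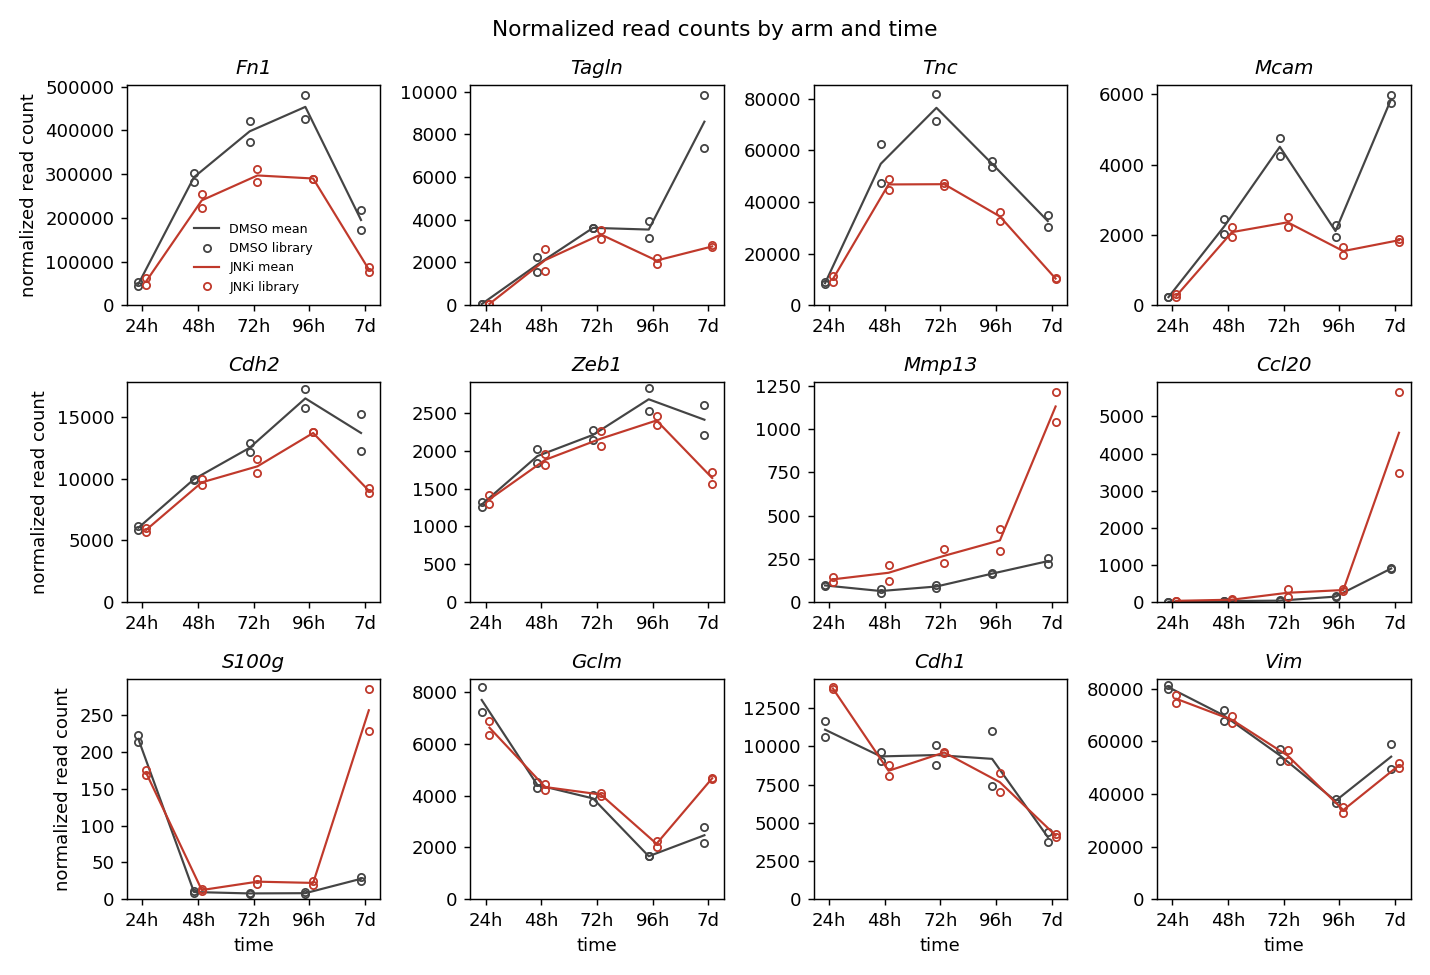
Normalized read counts (y axis, from 0) of 12 genes at each time (x axis, times evenly spaced) in DMSO (grey) and JNKi (red) cells, where circles are single libraries, 2 per group, and lines join the group means. Fn1 at 7 days averaged 195000 in DMSO and 81800 with JNKi, and Cdh1 4070 and 4180.

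Among the largest differences at 7 days, S100a9, a calprotectin subunit of myeloid and stressed epithelial cells, rose by 3.92 (SE 0.55), from 4.55 ± 0.636 to 84.4 ± 21.3 normalized reads (SD, n = 2). The bile acid receptor gene Gpbar1 fell by 2.15 (SE 0.24, limma adjusted p = 6.18e-05). The peptidoglycan recognition gene Pglyrp3 had a log2 difference of 3.26 (SE 0.64), with a limma adjusted p of 0.00461 that was 0.0562 without DMSO 7 d replicate 1 and 0.0581 without JNKi 7 d replicate 2. Hhipl1 had -2.63 (SE 0.74), with a limma adjusted p of 0.0314 that was 0.217 without DMSO 7 d replicate 1 and 0.358 without JNKi 7 d replicate 1, where the log2 difference was -1.36. Jun, a substrate of JNK, had -0.57 (SE 0.15, limma adjusted p = 0.0272), lost without DMSO 7 d replicate 1 (0.0771), DMSO 7 d replicate 2 (0.128) or JNKi 7 d replicate 1 (0.252). Rmrp, the RNA of an RNA-processing ribonuclease, had 5.21 (SE 1.34, limma adjusted p = 0.0211) and stood at 80.0 RPM in JNKi replicate 1 and 1.34 RPM in replicate 2 (log2 difference 2.26, adjusted p = 0.3 without JNKi 7 d replicate 1). Lars2, a mitochondrial leucyl-tRNA synthetase gene, took 15936 RPM in JNKi replicate 1 and 1699 RPM in replicate 2. Reads on the 514 silent receptor genes summed to 17.9 and 16.3 RPM in the JNKi libraries of 7 days, against 9.37 and 7.84 RPM in DMSO. With every library reduced to 9492324 reads, 16973 and 16996 genes had a read with JNKi against 16122 and 15880 with DMSO. By limma 1414 of 13896 genes changed at 7 days (673 higher and 741 lower), of which 177 were higher and 43 lower by at least 2-fold. Of these calls 47.6% were higher, against 37.4% with TMM rescaling and 59.7% with upper quartile rescaling. The edgeR test on the recovered reads called 1589 genes, 1340 of them shared with limma in the same direction. The count was 376 without DMSO replicate 1, 368 without JNKi replicate 1 and 563 without JNKi replicate 2 of 7 days, and 51 of the 80 named genes called at 7 days lost the call without at least 1 library of that time.

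**Figure D3:**
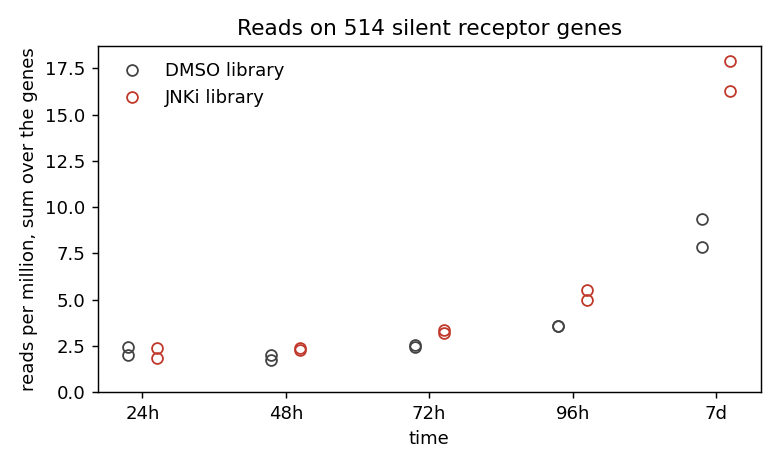
Reads on 514 olfactory and vomeronasal receptor genes (y axis, RPM summed over the genes, from 0) in each library by arm and time (x axis), 2 libraries per group. The DMSO libraries of 24 h lie at 2.47 and 2.0, those of 7 days at 9.37 and 7.84, and the JNKi libraries of 7 days at 17.9 and 16.3.

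Some lists passed camera at 7 days with a preset correlation and pointed down with JNKi, and none passed with an estimated correlation. Of 24 mesenchymal cytoskeleton and adhesion genes 0 rose, 8 fell and 16 did not pass the test (2 rose and 10 fell adjusted over the list alone), with the tropomyosin gene Tpm1 at -0.68 (SE 0.11) and the integrin gene Itgb1 at -0.64 (SE 0.10). The camera adjusted p of this list was 0.000136 (adjusted p = 0.288 with an estimated correlation). Among 35 extracellular matrix genes 10 fell and 25 did not pass (13 fell adjusted over the list alone), with the fibulin gene Fbln2 at -0.80 (SE 0.14) beside Tnc and Fn1. Camera gave the matrix genes 0.000701 (adjusted p = 0.392 with an estimated correlation). TGF-β signalling and feedback genes fell in 7 of 31 and rose in 0 (11 fell and 1 rose adjusted over the list alone), with the activin antagonist gene Fstl3 at -1.06 (SE 0.17) and the matricellular gene Ctgf at -1.02 (SE 0.15). Camera gave the TGF-β genes 1.45e-05 (adjusted p = 0.141 with an estimated correlation). EMT transcription factors fell in 2 of 11 (5 adjusted over the list alone), Zeb1 and Tead2, the latter at -0.40 (SE 0.09; limma adjusted p = 0.105 without JNKi 7 d replicate 2). Camera gave the EMT factors 0.00835 (adjusted p = 0.392 with an estimated correlation). YAP/TEAD targets fell in 3 of 20 (9 fell and 1 rose adjusted over the list alone), namely Ctgf, Crim1 (-0.73, SE 0.11) and Ankrd1 (-0.70, SE 0.15). The Ankrd1 call was lost without DMSO 7 d replicate 1 (0.0624) or JNKi 7 d replicate 1 (0.0993). Camera gave YAP/TEAD targets 0.00779 (adjusted p = 0.392 with an estimated correlation). Unfolded protein and amino acid response genes fell in 5 of 22 (9 adjusted over the list alone), with the transporter gene Slc7a5 at -0.77 (SE 0.17), a call lost without DMSO replicate 1 (-0.44, adjusted p = 0.179), JNKi replicate 1 (0.0693) or JNKi replicate 2 (0.0764) of 7 days. Camera gave the unfolded protein list 0.00835 (adjusted p = 0.538 with an estimated correlation). Ribosomal protein genes fell in 1 of 39 (1 adjusted over the list alone), with a median of -0.14 and a camera adjusted p of 0.00146 (adjusted p = 0.744 with an estimated correlation).

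Other lists that passed camera with the preset correlation pointed up with JNKi. Cholesterol biosynthesis genes rose in 8 of 23 and fell in 0 (12 and 0 adjusted over the list alone), with the sterol sensor gene Insig1 at 0.81 (SE 0.22) and the thiolase gene Acat2 at 0.72 (SE 0.21). Both calls were lost without DMSO replicate 1, JNKi replicate 1 or JNKi replicate 2 of 7 days (adjusted p from 0.0817 to 0.448), and without DMSO replicate 1 the log2 differences were 0.50 and 0.26. Camera gave the cholesterol genes 0.000308 (adjusted p = 0.587 with an estimated correlation). G2/M genes rose in 3 of 30 (4 adjusted over the list alone), with the mitotic kinesin gene Kif20a at 0.52 (SE 0.14), a call lost without DMSO replicate 1 (0.33, adjusted p = 0.284), JNKi replicate 1 (0.151) or JNKi replicate 2 (0.106) of 7 days. Camera gave the G2/M genes 0.00146 (adjusted p = 0.693 with an estimated correlation). Oxidative stress genes rose in 6 of 16 and fell in 0 (6 and 0 adjusted over the list alone), with Gclm, a subunit of the enzyme that starts glutathione synthesis, 1.91-fold higher (SE 0.10 on the log2 scale, limma adjusted p = 5.44e-05). Camera gave the oxidative stress genes 0.00873 (adjusted p = 0.288 with an estimated correlation). The p53 targets and cell cycle inhibitors rose in 5 and fell in 1 of 23 (8 and 1 adjusted over the list alone), with the cyclin gene Ccng1 at 0.63 (SE 0.11; limma adjusted p = 0.0506 without DMSO 7 d replicate 1). Camera gave the p53 list 0.0298 (adjusted p = 0.471 with an estimated correlation).

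The remaining lists did not pass camera at 7 days. Matrix proteases and inhibitors rose in 3 and fell in 8 of 25 (6 and 9 adjusted over the list alone), with a mean of 0.29, a median of -0.05 and a test that pointed down (camera adjusted p = 0.38). In that list the stromelysin gene Mmp3 was at 33.1 ± 3.68 normalized reads with JNKi and 2.7 ± 3.82 with DMSO (SD, n = 2), a log2 difference of 3.75 that was 2.41 without DMSO 7 d replicate 1 (limma adjusted p = 0.0533). Keratins rose in 4 and fell in 1 of 12 (4 and 2 adjusted over the list alone; camera adjusted p = 0.38), with the luminal keratin gene Krt18 at -0.72 (SE 0.13). The basal keratin gene Krt14 was at 1.90 (SE 0.42), lost without DMSO replicate 1, JNKi replicate 1 or JNKi replicate 2 of 7 days (adjusted p from 0.0517 to 0.0883). Epithelial junction and polarity genes rose in 2 and fell in 2 of 29 (2 and 2 adjusted over the list alone; camera adjusted p = 0.838). AP-1 family genes fell in 3 of 15 (3 adjusted over the list alone; camera adjusted p = 0.0677), among them Jun and the stress-induced factor gene Atf3 (-1.5, SE 0.40). The Atf3 call was lost without DMSO replicate 1 (0.208), JNKi replicate 1 (0.208) or JNKi replicate 2 (0.0603) of 7 days. JNK pathway genes rose in 1 and fell in 2 of 25 (3 and 2 adjusted over the list alone; camera adjusted p = 0.38), with a median of 0.02 that became -0.01 with TMM rescaling. Immediate-early genes rose in 1 and fell in 1 of 23 (1 and 1 adjusted over the list alone; camera adjusted p = 0.234), the latter being Srf, the serum response factor gene (-0.77, SE 0.11). DNA replication genes rose in 2 and fell in 1 of 30 (2 and 1 adjusted over the list alone; camera adjusted p = 0.539). Interferon-stimulated genes fell in 1 of 35 (1 adjusted over the list alone; camera adjusted p = 0.539), with a median of -0.08, a mean of 0.04 and a test that pointed down. NF-kB cytokines and chemokines rose in 2, Ccl7 and Ccl20, and fell in 2 of 24 (2 and 2 adjusted over the list alone; camera adjusted p = 0.563), with a median of 0.01 that became -0.02 with TMM rescaling. Aryl hydrocarbon receptor targets rose in 1 of 8 (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.856). Glycolysis and hypoxia genes fell in 1 of 25 (0 adjusted over the list alone; camera adjusted p = 0.506), and Wnt ligands, inhibitors and targets fell in 2 of 14 (2 adjusted over the list alone; camera adjusted p = 0.38).

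Mammary luminal markers rose in 1 and fell in 2 of 10 at 7 days (1 and 3 adjusted over the list alone; camera adjusted p = 0.303). Basal and myoepithelial markers rose in 2 and fell in 0 of 16 (2 and 1 adjusted over the list alone; camera adjusted p = 0.838), with a median of 0.03 that became 0 with TMM rescaling. Leukocyte markers rose in 1 of 7, endothelial markers fell in 1 of 6 and adipocyte markers changed in 0 of 3 (1, 1 and 0 adjusted over the list alone), with camera adjusted p values of 0.303, 0.856 and 0.38. Replication-dependent histones had a median of 0.73 with 0 of 16 past the test (0 adjusted over the list alone; camera adjusted p = 0.125). None of the 12 mitochondrially encoded genes listed was in the table.

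**Figure D4:**
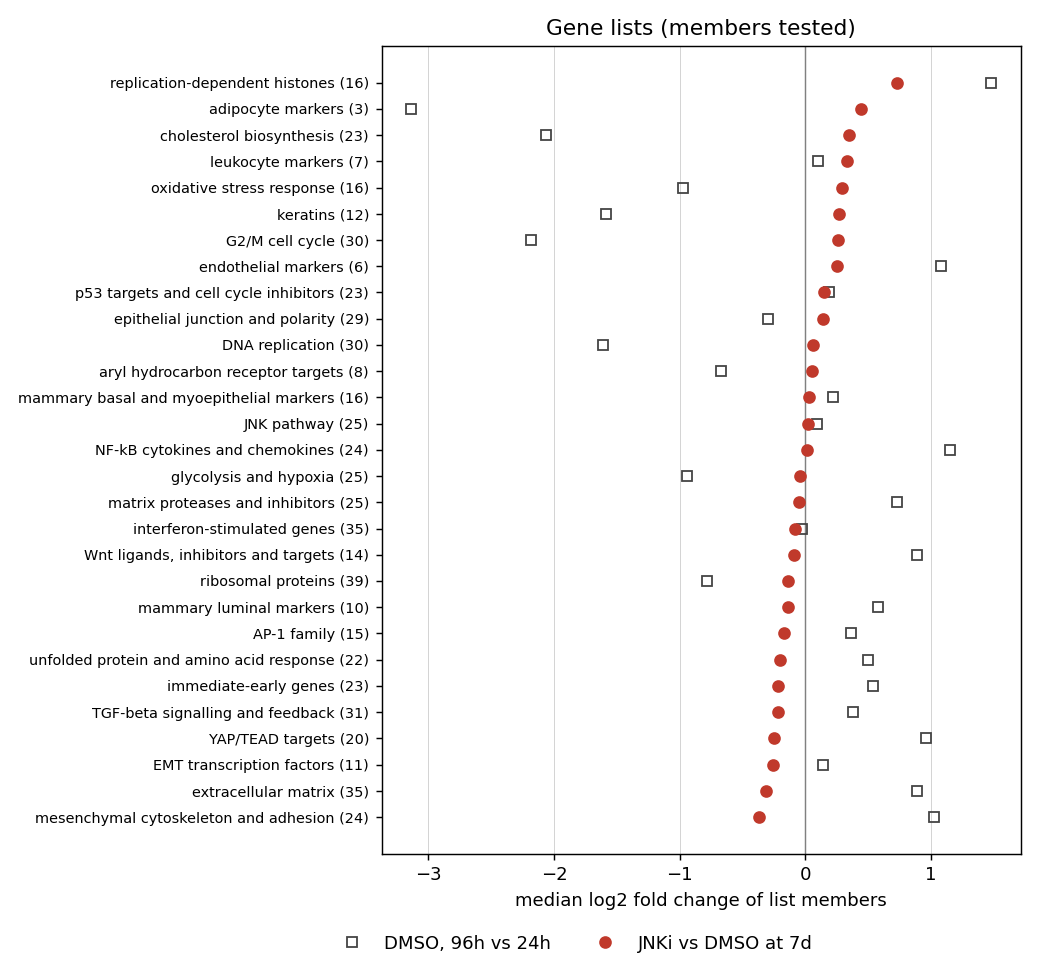
Median log2 fold change (x axis) of the tested members of each gene list (y axis, number of members in brackets) between DMSO at 96 h and 24 h (grey squares) and between JNKi and DMSO at 7 days (red circles), which share no library. Extracellular matrix genes lie at 0.89 and -0.31 and cholesterol biosynthesis genes at -2.06 and 0.35, while the small JNK pathway, NF-kB and basal marker medians at 7 days reach or cross 0 with TMM rescaling.

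The mean of the JNKi difference over the 5 times was tested next, gene by gene. Ccl20 rose by 1.65 (SE 0.16, limma adjusted p = 4.42e-05), Ccl7 by 1.53 (SE 0.16, adjusted p = 5.43e-05) and Mmp13 by 1.33 (SE 0.11, adjusted p = 1.52e-05) on the log2 scale, from 10 libraries per arm. Tnc fell by 0.61 (SE 0.06, limma adjusted p = 4.42e-05). Fn1 was at -0.49 (SE 0.08), Cdh2 at -0.22 (SE 0.04) and Il11, a cytokine gene induced by TGF-β, at -0.61 (SE 0.10), with limma adjusted p values of 0.00249, 0.00586 and 0.00249. The p53-responsive genes Fas (0.71, SE 0.12) and Ccng1 (0.45, SE 0.05) rose, with limma adjusted p values of 0.00331 and 0.000159. Other genes higher with the same sign at all 5 times were the transporter genes Slc29a4 (1.44) and Slc6a12 (1.41), the carboxylesterase gene Ces2e (1.29, one of several close copies), Pappa2 (1.25) and the acute phase gene Saa3 (1.27). Lower with the same sign at all 5 times were Angptl2 (-0.68), Adamtsl2 (-0.63), Adamts16 (-0.84), Col6a3 (-0.50), Loxl1 (-0.48), Pde8a (-0.46) and Mical1 (-0.45). Loxl1 lost its call without JNKi 7 d replicate 1 (0.0511), and Col6a3 without that library (0.0618), DMSO 96 h replicate 1 (0.0533) or JNKi 96 h replicate 2 (0.0591). Adamts16 lost it without replicate 2 of DMSO 48 h, 72 h or 96 h or of JNKi 96 h or 7 d (adjusted p from 0.052 to 0.0567). Saa3 lost it without replicate 1 of DMSO 24 h, 48 h or 72 h, or replicate 2 of DMSO 96 h or 7 d or of JNKi 24 h, 72 h, 96 h or 7 d (adjusted p from 0.0503 to 0.0644). Slc6a12 had an adjusted p of 0.0572 with edgeR, and Pappa2 0.114 after subtraction of the higher background estimate. Jun (-0.10, limma adjusted p = 0.457), Cdh1 (0.00, adjusted p = 0.995), Vim (-0.07, adjusted p = 0.456) and Snai1 (-0.05, adjusted p = 0.846) did not pass. Neither did Zeb1 (-0.14, limma adjusted p = 0.0747), Zeb2 (-0.05, adjusted p = 0.636), Mapk8 (-0.02, adjusted p = 0.886) or Mapk9 (0.03, adjusted p = 0.721).

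By group, extracellular matrix genes fell in 11 of 35 and rose in 0 in this mean (16 and 0 adjusted over the list alone). Camera gave matrix genes 3.62e-09 (adjusted p = 0.0723 with an estimated correlation). Mesenchymal cytoskeleton and adhesion genes fell in 8 and rose in 1 of 24 (13 and 1 adjusted over the list alone), the 1 that rose being Acta2 (0.51, SE 0.13). The Acta2 call was lost without replicate 1 of DMSO 48 h, 72 h, 96 h or 7 d or of JNKi 24 h, 96 h or 7 d, or replicate 2 of DMSO 24 h or of JNKi 48 h, 72 h or 7 d (adjusted p from 0.053 to 0.0757), and it was 0.135 with edgeR. Camera gave mesenchymal genes 5.16e-07 (adjusted p = 0.0723 with an estimated correlation). TGF-β signalling genes fell in 5 of 31 (8 fell and 2 rose adjusted over the list alone), with a camera adjusted p of 0.000891 (adjusted p = 0.176 with an estimated correlation). The p53 targets and cell cycle inhibitors rose in 8 of 23 and fell in 0 (9 and 0 adjusted over the list alone), with a camera adjusted p of 5.16e-07 (adjusted p = 0.0723 with an estimated correlation). NF-kB cytokines and chemokines rose in 7 and fell in 1 of 24 (9 and 1 adjusted over the list alone), with a camera adjusted p of 0.000133 (adjusted p = 0.31 with an estimated correlation). Cholesterol biosynthesis genes rose in 5 of 23 (14 rose and 1 fell adjusted over the list alone), with a camera adjusted p of 1.73e-05 (adjusted p = 0.414 with an estimated correlation). Histones (1 of 16 rose, 0.00036) and interferon-stimulated genes (1 of 35 rose, 0.0481) also passed camera pointing up. DNA replication (1 of 30 fell, 0.00336), EMT transcription factors (2 of 11 fell, 0.00831), unfolded protein (1 of 22 fell, 0.0128) and YAP/TEAD genes (1 of 20 fell, 0.0202) passed pointing down. With an estimated correlation these lists had adjusted p values from 0.31 to 0.688. Adjusted over each list alone, 5 histones and 1 interferon-stimulated gene rose, and 4, 3, 5 and 1 genes of the lists pointing down fell. In total 663 genes changed in the mean (341 higher and 322 lower), 445 of them also called at 7 days with the same sign, and 51.4% were higher against 43% with TMM rescaling and 66.5% with upper quartile rescaling. The count was 393 without JNKi 96 h replicate 1, 403 without JNKi 96 h replicate 2, 406 without JNKi 7 d replicate 1 and 415 without JNKi 7 d replicate 2.

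With the 7 day difference taken out of the mean, a choice made after seeing the data, Ccl20 (1.49, SE 0.18, limma adjusted p = 0.00132), Mmp13 (1.10, SE 0.12, adjusted p = 0.0013) and Fas (0.72, SE 0.14, adjusted p = 0.0314) rose over 24 to 96 h. Ltbp3 (-0.30, SE 0.04, limma adjusted p = 0.00399) and Tnc (-0.34, SE 0.07, adjusted p = 0.0396) fell. The mesenchymal list member Acta2, at -0.37 at 7 days without passing the test there, rose (0.73, SE 0.14, limma adjusted p = 0.0396). These were among 48 genes that changed (30 higher and 18 lower), of which 31 were also called at 7 days with the same sign. The share higher was 62.5%, against 59.2% with TMM rescaling and 80.5% with upper quartile rescaling. Other settings gave 18 genes (robust variances), 22 (no filter), 7 (a log2 change of at least 1) or 150 (DESeq2), and both fits with a block gave more than 48, the block within each time the most of all. The count of 48 was 14 without JNKi 96 h replicate 1, 15 without DMSO 72 h replicate 2, 19 without JNKi 96 h replicate 2, 23 without DMSO 48 h, DMSO 96 h or JNKi 24 h replicate 2, 25 without either JNKi 7 d library and 31 without either JNKi 72 h library.

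Whether the JNKi difference changed between times was tested directly. Mcam differed from DMSO by 0.18 at 24 h and -1.67 at 7 days (SE 0.14 each), Tnc by 0.23 and -1.67 (SE 0.13 each) and S100g by -0.34 and 3.16 (SE 0.27 each) on the log2 scale. The limma adjusted p values for the difference between times were 0.00211, 0.00211 and 0.00297. Tagln went from 0.25 at 24 h to -1.63 at 7 days (SE 0.22 each, limma adjusted p = 0.0271), Gclm from -0.21 to 0.93 (SE 0.10 each, adjusted p = 0.00564) and Crim1 from 0.18 to -0.73 (SE 0.11 each, adjusted p = 0.0337). In total 45 genes passed this test, and 44 of them had their largest JNKi difference at 7 days. The count depended on the fit, at 16 with robust variances, 101 with the replicate number as a block and 358 with DESeq2. It was 1148 with a block within each time, a fit chosen after seeing the data. The JNKi difference at 7 days departed from the mean of the earlier 4 in 464 genes (230 higher and 234 lower). Across 13896 genes, which are not independent replicates, the differences at 7 days correlated with those at 24, 48, 72 and 96 h at Pearson r = 0.11, 0.17, 0.29 and 0.34 (Spearman rho 0.05, 0.13, 0.21 and 0.30). The count of 45 was 8 and 9 without JNKi 7 d replicate 2 and replicate 1, 13 without DMSO 7 d replicate 1 and 80 without DMSO 7 d replicate 2. It was 25 without DMSO 24 h replicate 2, 26 without DMSO 48 h replicate 1, 23 without DMSO 72 h replicate 2, 27 without JNKi 24 h replicate 1, and 26 and 29 without JNKi 96 h replicate 1 and replicate 2.

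The last comparison set the change with time in vehicle-treated cells beside the JNKi difference, using DMSO at 96 h against 24 h and JNKi against DMSO at 7 days, which share no library. This choice was made after seeing the data. Tagln led the genes that rose with time and fell with JNKi, with Stmn4 (-1.39 at 7 days), Hhipl1, Lrrc32 (-1.41), Wisp2 (-0.73) and AU018091 (-1.31), and each of these except Tagln lost its 7 day call without at least 1 library of that time. Genes that fell with time and rose with JNKi were led by S100a9, S100g, S100a8 (2.75, SE 0.47), Serpina1b (2.17, SE 0.36, one of several near-identical copies), Eps8l3 (3.25, SE 0.49, or 2.43 and 4.07 without DMSO 7 d replicate 1 and replicate 2) and Apoc2 (2.51, SE 0.69). The Apoc2 call was lost without DMSO replicate 1, JNKi replicate 1 or JNKi replicate 2 of 7 days (adjusted p from 0.1 to 0.367), and its log2 difference was 1.02 without DMSO replicate 1 and 3.99 without DMSO replicate 2. Of the 741 genes lowered by JNKi, 439 had risen with time, where 242 were expected from independent lists (odds ratio 3.2, 95% interval 2.75 to 3.74, two-sided Fisher's exact test p = 2.4e-52, adjusted over 4 direction pairs 9.6e-52). Of the 673 genes raised by JNKi, 327 had fallen with time against 206 expected (odds ratio 2.24, 95% interval 1.91 to 2.63, adjusted p = 2.14e-23). Genes that moved the same way in both were fewer than expected, at 126 higher against 220 and 117 lower against 226 (odds ratios 0.459 and 0.41). The odds ratio of 3.2 was 2.12 without DMSO 7 d replicate 1, 6.4 without DMSO 7 d replicate 2 and 11.2 among genes changed by at least 2-fold in both. Genes are not independent, so these p values describe the lists of genes.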

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

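The contrast of 7 days with the earlier times, the fit on the 7 day libraries alone, the block within each time, the background tests of DMSO at 7 days against 24 h, of single families or with 2 left out, and of the raised genes, and the structural RNA ratio with Snord17 were chosen only after the result was seen. A difference in the JNKi effect between times, by limma's test of that difference, marked 45 genes, and the contrast of 7 days with the mean of the 4 earlier effects marked 464. Adhesion and matrix genes were among the 45, with adjusted p values for the difference of 0.00211 for Mcam, 0.00211 for Tnc and 0.0228 for Col5a1. The contractile gene Tagln had 0.0271 and the YAP/TEAD target Crim1 0.0337. Epithelial and metabolic genes with such a difference were S100g (0.00297), Gclm (0.00564) and Gpbar1 (0.016). Groups held 2 libraries, so single libraries were not tested against their group.

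The first pattern was that JNKi changed 1414 genes at 7 days and at most 10 at an earlier time by limma. DESeq2 called 105 at 72 h, and a block within each time gave 15 to 334 at earlier times and 3522 at 7 days. The difference between replicates correlated between arms at 0.21 to 0.4 earlier and at 0.04 at 7 days. Among 9605 genes with a mean of at least 200 these values were 0.53 to 0.73 and 0.07. The fit without a block counts this likeness as noise, which may lower its earlier counts. A likeness between same-number libraries cancels in arm differences taken within a number. Across 7898 genes these differences correlated between numbers at 0.5, 0.23, 0.6 and 0.41 at 24, 48, 72 and 96 h and at 0.65 at 7 days. With the numbers crossed, the correlations were -0.51, -0.43, -0.22, -0.13 and 0.61. Differences between arms that both numbers shared were thus present before 7 days too. How far the fit without a block widened the gap stays open, and 7 days had the most calls with the block too. Depth was excluded as the cause, since 936 genes were called at 7 days and at most 4 at an earlier time with every library thinned to the same depth, and so was a wider spread at 7 days, since a fit on its 4 libraries alone called 1661. A single aberrant library was excluded as the whole cause, since effects from disjoint pairs of 7 day libraries correlated across 7898 genes at 0.61 or more, although the count was 376 without DMSO replicate 1, 368 without JNKi replicate 1 and 563 without JNKi replicate 2. Handling or library preparation that differed between the arms at 7 days stays open, since the labels give no batch, and so does a late effect of the inhibitor itself, which was not tested.

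For the mean over the 5 times, 2 of 100 splits within times, the real one included, gave as many calls as the 663 observed. This does not exclude chance assignment of libraries to arms. Libraries of the same time and number resembled each other across arms, so splits that break up or join such libraries are not comparable with the real one. The highest other split gave 1409. It parted 24 h and 48 h by replicate number and 72 h, 96 h and 7 days by arm, so it points to a structure of the samples in which libraries of the same time and number resemble each other across arms, and a fit with a block within each time gave 2198.

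The second pattern was the rise of reads on silent receptor genes at 7 days, highest with JNKi. A uniform background of reads along the genome may account for the difference between the arms at 7 days, since reads on 149 silent genes of other families stood 2.27-fold higher with JNKi (95% counting interval 1.93 to 2.68) and those on receptor genes 2.01-fold (1.79 to 2.25). With 2 families left out this ratio ran from 2.09 to 2.67, with an interval above 2.01 in 9 of 45 pairs. Each of these 9 pairs left out the Prl family, with ratios from 2.52 to 2.67. Prl alone stood at 1.5 (1.08 to 2.1). A uniform background between the arms is thus less certain than the pooled ratio makes it appear. For the rise from 24 h to 7 days in DMSO it stays open, since the ratio was 2.1 (1.62 to 2.75) for other families and 3.71 (2.97 to 4.69) for receptor genes, with 42 of 45 intervals below 3.71 when 2 families were left out, but 3 included it (3.66, 2.5 to 5.54, without Cyp2c and Mrgpr), and these families, at 0.724 and 1.28, had more reads per gene at 24 h (0.504 RPM on 12 genes and 0.624 RPM on 17) than the receptors (2.23 RPM on 514), while Krtap was at 5.31 (2.25 to 15.2). Of the genes raised by JNKi, 95.8% stayed past the test after the higher background was subtracted, so background of that size did not account for most of them. That estimate was 1.127 and 1.431 normalized reads per kb in the JNKi libraries of 7 days. It came from genes chosen to be under 1 RPM, so it may be low. Only genes with a mean of at least 10 in at least 1 group were tested. Low transcription of silent genes stays open as an untested biological explanation.

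The third pattern was that reads on Lars2 and on the structural RNA genes Rmrp and Rpph1 were high in JNKi 7 d replicate 1, with Rpph1 at 26.1 RPM there and 0.52 RPM in replicate 2, as were Snord17 (11.17 and 0.57 RPM) and Mtrnr2l (162.97 and 39.23 RPM). Carry-over shared by small structural RNA genes in general was not seen in 104 other such genes, a set without Rmrp, Rpph1 and Snord17. Together they were 1.18 times as high in replicate 1 (1.28 with Snord17), with 52 of 95 higher. Their 123 RPM lay among the other libraries (74.9 to 180). This set holds neither Lars2 nor Mtrnr2l, so it says nothing about the reads on those genes. Carry-over of a few structural RNAs or of other kinds of RNA was not tested and stays open. Another difference in the preparation of that library stays open as untested, and no biological explanation was tested.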

How the results depend on the processing

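The block within each time, both background subtractions, the mean over 24 to 96 h and the replacement overlap were chosen only after the data were seen. The overlap odds ratio (3.2) stayed above 1 under every alternative run, at up to 11.2. The share of calls that were higher crossed 50% in some settings, among them at 7 days (47.6%) 59.7% with upper quartile rescaling, 58.2% with no filter, 56.1% with a pseudocount of 8, 54.5% with the 2 groups alone and 51.8% with robust variances, and in the mean (51.4%) 43% with TMM, 45.1% with edgeR and 45.2% with DESeq2. In DMSO from 24 h to 7 days this share (53.4%) was 46.8% with a group mean of at least 50 and 49.9% with DESeq2. The mean over 24 to 96 h (48) gave 18 genes with robust variances, 22 with no filter, 93 with the replicate number as a block, 778 with a block within each time, 150 with DESeq2 and 7 with a log2 change of at least 1. Of 234 named gene calls, 151 stayed past the test in all alternatives. The count at 24 h (0) was 6 with a pseudocount of 0.5, 5 with TMM, 3 with robust variances, 1 with DESeq2 and 6 with the higher background. At 48 h (0) it was 2 with DESeq2. At 72 h (10) it was 2 with robust variances, 6 with a log2 change of at least 1, 0 with the 2 groups alone and 105 with DESeq2. At 96 h (1) it was 34 with DESeq2 and 0 with a pseudocount of 8, no filter, robust variances, the 2 groups alone or the higher background. A log2 change of at least 1, which counts fewer genes by construction, gave 220 at 7 days (1414), 48 in the mean (663) and 3021 in DMSO (8329). Genes that differed between times (45) were 16 with robust variances and 358 with DESeq2. Lists past camera at 7 days (11) were 0 with an estimated correlation and 7 with fry. As a check on pairing, the difference between replicates was correlated across genes between arms, at 0.26 at 24 h, 0.21 at 48 h, 0.4 at 72 h, 0.21 at 96 h and 0.04 at 7 days, and at 0.73, 0.59, 0.72, 0.53 and 0.07 among 9605 genes with a mean of at least 200. With the replicate number as a block, 0 genes changed at 96 h and 101 differed between times. With a block within each time the counts were 19, 15, 334, 99 and 3522 at 24 h, 48 h, 72 h, 96 h and 7 days, 2198 in the mean and 1148 between times. With 1 library left out, where the lone library of a group is assumed to vary like the others, the counts ran from 0 to 13 at 24 h, 0 to 4 at 48 h, 0 to 16 at 72 h, 0 to 1 at 96 h, 368 to 1519 at 7 days, 393 to 754 in the mean, 8 to 80 between times and 6520 to 8412 in DMSO, and the odds ratio from 2.12 to 6.4. The cause was not tested for the settings other than fewer libraries and a larger fold. Depth limits the 7 day comparison through JNKi replicate 1 with 9.5 M reads, and 936 genes were called with all libraries thinned to that depth. The planned comparisons of the time course with 0 h, its overlap with JNKi and their alternatives, and the alternatives for pooled columns, were not run.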

Other observations

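All genes here except Egln3, which the naming rule gave from the glycolysis and hypoxia list, were named after their values were seen. Leaving out single libraries was not run gene by gene for the values given here. Among single genes whose JNKi effect differed between times, the LIM protein gene Csrp2 had a log2 difference at 7 days of -1.35 (SE 0.16). Enah, which extends filaments, had -0.85 (SE 0.08), the focal adhesion gene Zyx -0.85 (SE 0.09) and Pdlim7 -0.71 (SE 0.08). In this order, the limma adjusted p values for the difference between times were 0.0361, 0.00561, 0.0271 and 0.0439. The perlecan gene Hspg2 was at -0.82 and the collagen gene Col4a1 at -0.80 at 7 days, with adjusted p values for the difference between times of 0.00211 and 0.0439. Higher at 7 days were the cell adhesion gene Alcam (1.24, SE 0.13), the pyrophosphate exporter gene Ank (0.93, SE 0.08), the glucuronate synthesis gene Ugdh (0.80, SE 0.08) and the ferritin gene Fth1 (0.75, SE 0.10).

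Single genes called over 24 to 96 h were also read. The receptor gene Eda2r was at 0.41, the desmosomal p53 target Perp at 0.31 (SE 0.05) and the invariant chain gene Cd74 at 0.92 (SE 0.17). Their limma adjusted p values were 0.0314, 0.0198 and 0.0314. The oxygen-sensing hydroxylase gene Egln3 was at 0.62 (SE 0.08, limma adjusted p = 0.00132). Lower were the proteoglycan gene Gpc1 (-0.24, adjusted p = 0.0065) and the receptor kinase gene Erbb2 (-0.19, SE 0.04, adjusted p = 0.0314). The count of 48 genes in this mean was 14 to 31 without any 1 of the 10 libraries named for it.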
